A study of Mus musculus with 291 samples.

How the data were processed

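Cells sorted from the retinas of mice aged 17 days with the Vsx2-GFP transgene were processed as single cells (96 from each of 3 retinas, 1a, 2a and 2b) and as bulk samples of 10000 cells (1 from each retina). Sequencing libraries were made by Smart-seq2. The labels do not state the gate of the sort.

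The expected counts per gene, not scaled by depth, are RSEM values deposited by the authors. The TPM values (a transcript abundance scaled by effective transcript length to a fixed total per library) were also deposited by the authors. The submitters' processing notes name bcl2fastq, TopHat2 2.0.10, RSEM 1.2.28 and genome build mm10; the role and settings of each tool and the gene annotation are not stated there. Both tables hold 32813 genes and 291 libraries. The 4 genes with a repeated name were left out, which leaves 32809, and 27 names have the form of a date and were kept as they stand. Positions come from GENCODE mouse release 21, which held 30159 of the names (91.9%) and 214 of 218 named genes.

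A gene counted as detected at an expected count of at least 1. A single-cell library passed with at least 1000 detected genes and 50000 expected counts, which 249 of 288 did; no program for calling doublets was run. The passing cells had a median of 812931 counts and the bulk libraries 10611721 to 11497513. Any 2 bulk libraries differed by more than counting error, with a chi-square over degrees of freedom of 11.1 to 20.8. For the comparison of detection, rounded counts were thinned at random to 50000 per library. Shares of cells carry exact Clopper-Pearson 95% intervals.

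Cells were clustered with scanpy 1.11.5 and igraph 0.11.9 on log2(CPM+1) of 116 cell type marker genes, with 10 principal components, 15 neighbours and a Leiden resolution of 1, which gave 10 clusters. The markers form 18 lists, and 24 other lists of 665 genes in all cover pathways and gene families. A cluster was named when the mean log2(CPM+1) of a marker list in it was above 5. The lists were read in this order: Müller glia, rod photoreceptor (left unnamed), ON bipolar (rod bipolar-like where the rod bipolar list was above 5 too, otherwise ON cone bipolar-like), and cone bipolar with the OFF list above the ON list. Limits of 4 for the rod bipolar list and 3.5 for the rod photoreceptor list were used at first. They were replaced by 5 after the shares and the agreement under other settings had been seen. The classes were the same under both sets of limits in 249 of 249 cells. With the change, agreement of classes with those of other settings moved from 88.4% to 92.0% of cells for clusters on variable genes, from 92.4% to 85.1% at a Leiden resolution of 0.5 and from 89.2% to 98.0% at 2. It was 94.4% without a cell filter, 95.1% with cells of at least 2000 genes and 96.3% without well G12, before and after. The unnamed cluster held 6 cells of each retina.

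In 4 comparisons the counts of all passing cells of a retina, or of its cells of 1 class, were summed and rounded to whole numbers, so that the replicate is the retina. The comparisons were pooled cells with bulk, bipolar-like with Müller glia-like, rod with cone bipolar-like and ON with OFF cone bipolar-like cells. Each was tested in edgeR 4.0.16 (R 4.3.3) with TMM normalisation, filterByExpr and the quasi-likelihood F test, at a Benjamini-Hochberg false discovery rate of 0.05. In the comparisons of classes the 116 marker genes were left out, since they had formed the clusters. A comparison was to be run only with at least 5 cells of each class in every retina; retina 2a has 4 Müller glia-like cells, and a minimum of 4 was used there. A comparison of rod photoreceptor-like with bipolar-like cells was planned too. It was not run, since the cluster with rod markers was left unnamed. That cluster held 6 cells of each retina, well G12 included.

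Sums with the same retina name come from the same retina, so the names pair the samples. The check of the pairing was Pearson's r across genes between the departures of 2 sums from their group means. It was 0.102, 0.054 and 0.018 within retinas for pooled cells with bulk, and between 0.013 and 0.055 in the comparisons of classes; between retinas it ran from -0.091 to 0.034 over all comparisons. Values with retina as a block are given beside the gene counts.

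Gene lists were tested with limma 3.58.1: camera on voom values with a preset correlation of 0.01, camera with the correlation estimated, and fry. Adjusted p-values are over the lists of a comparison. A list call in the report is a camera call, and 0 of the calls hold with an estimated correlation. Lists with an estimate below the preset 0.01 lost their call too, as GABA and glycine receptors in bipolar-like with Müller glia-like cells (-0.024). Losing a call there is thus no measure of correlation between genes alone. Named genes follow a rule: among genes under the false discovery rate, moving the same way in 3 of 3 retinas, with a mean log2 CPM of at least 5, the 8 largest rises and the 8 largest falls; up to 4 called members of each list, or else the member with the highest mean; and Vsx2. The text names a part of these genes. Where all libraries of a group had 0 counts, the fold is a bound against 3 counts per library; with 1 to 3 counts, the ratio of summed levels is given with its 95% Poisson interval.

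Correlations across genes used log2(TPM+1), with 100 random draws of cells for each number of cells and the mean TPM of the drawn cells. The alternatives were DESeq2 1.42.0, RLE size factors, limma-trend on log2 of mean CPM or mean TPM of the cells plus 1, other filters, retina as a block, other cluster settings and leaving out each retina. No TMM factors were applied in the limma-trend settings. The rules for lists, named genes, tests and most alternatives were set before the data were examined. Alternatives without well G12, the unnamed cluster or satellite genes, and the minimum of 4 cells, were added after.

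The models were tested on simulated data with the spread of each comparison and 200 changed genes, 50 at each fold. A first version with a common dispersion and folds from 1.5 to 8 recovered few genes; trended dispersions and folds of 2, 4, 8 and 64 then replaced it. For pooled cells with bulk 26%, 54%, 74% and 96% of the genes changed by 2-, 4-, 8- and 64-fold were recovered, with 5 unchanged genes called. At the same folds it was 0%, 0%, 2% and 52% for bipolar-like with Müller glia-like cells. For rod with cone it was 0%, 18%, 42% and 64%, and for ON with OFF cone bipolar-like cells 0%, 4%, 26% and 60%. No changed gene was called with the wrong sign. These shares hold for 200 changed genes and for trended dispersions, which leave out spread between genes of like level. In the data edgeR called 1804, 1196, 382 and 9 genes, and recovery at other numbers of changed genes was not tested.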

Results

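The transcriptomes of single retinal cells and of bulk samples of sorted retinal cells were measured by Smart-seq2, a method that amplifies full-length cDNA from the poly(A) RNA of 1 cell or a few. The mice were 17 days old and carried Vsx2-GFP, a transgene that reports Vsx2, a homeobox gene of bipolar cells and Müller glia. From each of 3 retinas, named 1a, 2a and 2b, 96 single-cell libraries and 1 bulk library of 10000 cells were made, 291 libraries in all. The labels do not say whether retinas 2a and 2b came from 1 animal, and the p-values below treat the 3 retinas as independent. The spread they measure lies between the sums or libraries of these retinas. It includes the draw of cells in each sum as well as any difference between retinas.

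Of the 288 single-cell libraries, 249 held at least 1000 genes and 50000 expected counts: 88 from retina 1a, 83 from 2a and 78 from 2b. These cells had between 240056 and 1312412 expected counts (median 812931) and a median of 4994 detected genes. The 39 libraries under these limits had between 16 and 422310 counts. The bulk libraries had 10611721 to 11497513 counts and 18075 to 18814 detected genes. Intervals and detection limits below cover counting error only, since reads without molecular identifiers are not independent molecules.

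Most of the passing cells carried transcripts of bipolar cells, the interneurons between photoreceptors and ganglion cells. Clusters with the markers of rod bipolar cells held 43.5% ± 3.32 (SD, n = 3) of the cells of a retina, 108 cells in all. ON cone bipolar-like clusters held 25.3% ± 2.09 (63 cells) and OFF cone bipolar-like clusters 14.4% ± 1.45 (36 cells), so that the 3 bipolar-like classes came to 83.2% ± 4.77. At a Leiden resolution of 0.5 the OFF cone bipolar-like share was 6.89%, the 3 classes came to 75.7%, and 37 cells (14.77%) stood in clusters that fit no class, while no cells were held by a cluster above the limit for rod markers. Müller glia-like cells, with the clustering markers Apoe, Slc1a3 and Rlbp1 among the leading genes of their cluster, held 9.52% ± 5.0 (24 cells). Their number was 13 of 88 in retina 1a (14.8%, exact 95% interval 8.11 to 23.9), 4 of 83 in 2a (4.82%, 1.33 to 11.9) and 7 of 78 in 2b (8.97%, 3.68 to 17.6). A further cluster held 6 cells of each retina, or 7.25% ± 0.44. Its first genes were the rod genes Rho, Pdc and Gnb1 by difference in mean log level, and Rps3a3 and Hbb-bh1 by fold. It was left without a name by the rule for clusters with rod markers above the limit, and it held cells with and without Vsx2. Of these 18 libraries 3 come from well G12, which holds embryonic globin transcripts on all 3 plates. When clusters were made without these 3, ON cone bipolar-like clusters held 54 cells (21.93%) and the rod-marker cluster 24 (9.81%). The 3 bipolar-like classes then came to 80.56%. No cluster was led by amacrine, horizontal or ganglion cell markers, though 2 cells of the unnamed cluster reached 100 CPM of the amacrine markers Gad1 or Tfap2b. The retinas are samples of 1 kind, so no test between them was made, and no program for calling doublets was run.

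**Figure D1:**
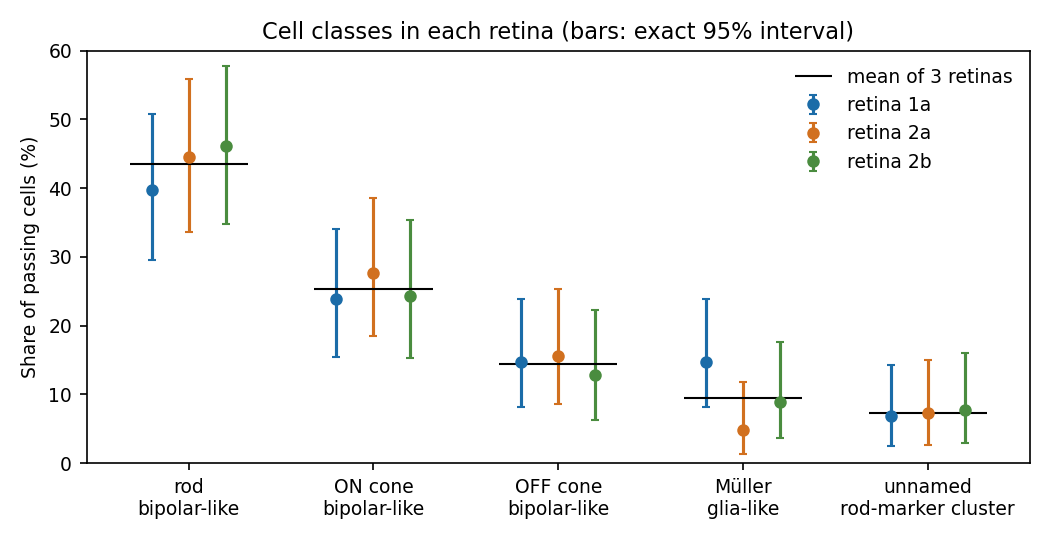
Share of the passing cells of each retina (vertical axis, percent) in each class (horizontal axis); points are retinas, bars the exact 95% intervals and black lines the means of 3 retinas. Rod bipolar-like cells were the largest class, with a mean of 43.5%, and the Müller glia-like share spread from 4.82% to 14.8%.

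Vsx2 itself was found in 54 of 54, 30 of 30 and 24 of 24 cells of the 3 rod bipolar-like clusters and in 23 of 24 Müller glia-like cells. Its mean level in Müller glia-like cells was 316 ± 59.1 CPM (SD, n = 3), where CPM is a count scaled by the total of its library. In the bipolar-like clusters it ran from 379 ± 148 in an ON cone cluster led by Vsx1, Reln and Cck to 1781 ± 477 in a rod bipolar-like cluster. The gene lies on chromosome 12, 84569762 to 84595457 (mm10).

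Single cells showed fewer genes than bulk at the same depth. After thinning every library to 50000 counts, the median passing cell held 3061 ± 57.2 genes (SD over 3 retinas) and a bulk library 9174 ± 163. At full depth these numbers were 4999 ± 20.1 and 18336 ± 414. The 78 to 88 passing cells of 1 retina together, well G12 included, showed 19741 ± 183 genes. That number was not thinned, and the summed depth of the cells is above that of a bulk library. The median at 50000 counts was 3155 genes in ON cone bipolar-like cells, 3024 in rod bipolar-like, 2944 in OFF cone bipolar-like and 2925 in Müller glia-like cells.

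Averaging over cells brought the single cells close to bulk. Pearson's r of log2(TPM+1) across 32809 genes between 1 cell and the bulk library of its retina was 0.527 ± 0.005 (SD, n = 3). It was 0.829 ± 0.008 for the mean of 10 cells, 0.913 ± 0.006 for 40 and 0.932 ± 0.006 for all cells of a retina. Against the bulk libraries of the other retinas the mean of all cells gave 0.930 ± 0.007. Own bulk stood above the mean of the other 2 by 0.0015 in retina 1a, 0.0042 in 2a and 0.0007 in 2b, while bulk 2a was closer to the cells of 2b (0.9329) than their own (0.9314). Pairs of bulk libraries gave 0.974, 0.975 and 0.978. Spearman's rho for all cells was 0.885 ± 0.007. Genes are not independent replicates, so no p-value is given for these correlations.

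**Figure D2:**
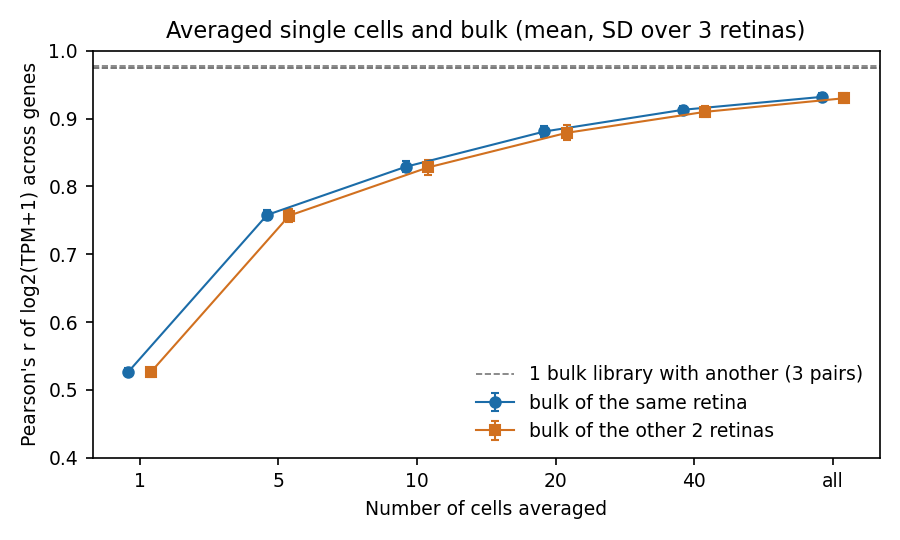
Pearson's r across genes of log2(TPM+1) between averaged single cells and bulk (vertical axis) by the number of cells averaged (horizontal axis, spaced by category); points are means and bars the SD over 3 retinas, and dashed lines are the 3 pairs of bulk libraries. The mean of all cells reached 0.932 with the bulk of the same retina and 0.930 with the others.

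The bulk libraries serve as the control for the single cells, and the pooled counts of the cells of each retina were compared with them. In the 4 comparisons, levels of pools, bulk and class sums are normalised CPM, scaled by library totals times TMM factors. Levels of single cells, clusters and wells, and those outside the comparisons, are plain CPM without these factors. Mitochondrial transcripts were higher in the pools: mt-Co3, a subunit of cytochrome c oxidase, stood at 3639.7 ± 584 (SD, n = 3) normalised CPM in pools and 409 ± 22.3 in bulk (log2 fold change 3.15, adjusted p = 6.84e-05). All mitochondrially encoded genes together took 4.46% ± 0.29 of the counts of cells and 1.31% ± 0.14 of bulk. Among the genes that fell, Syp, which encodes synaptophysin, was at 42.5 ± 4.06 CPM in pools and 267 ± 55.0 in bulk (log2 fold change -2.65, adjusted p = 0.00041), and the vesicle glycoprotein genes Sv2b and Sv2a fell by 1.30 and 0.99 on the log2 scale (adjusted p = 0.00242 and 0.0026). Over the 35 synaptic vesicle and ribbon genes, 4 were higher, 7 lower and 24 not called. The list gave 4 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.76, adjusted p = 0.989 with an estimated correlation). Its median was 0.01 and its mean -0.09, and the test points down. Vsx2 was at 1267 ± 30.3 normalised CPM in pools and 1493 ± 86.7 in bulk (log2 fold change -0.24, adjusted p = 0.122). In plain CPM the mean of the passing cells was 1068.9 ± 77.2 and that of bulk 1757.0 ± 87.5.

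The highest rises by the rule for named genes were in genes annotated over satellite repeat DNA. Gm10800 (chromosome 2, 98666547 to 98667301) stood at 90718 ± 33726 CPM in pools and 17.2 ± 11.8 in bulk (log2 fold change 12.36, adjusted p = 0.000343), and Gm26870 (chromosome 9, 3000282 to 3038313) at 64126 ± 24824 and 9.64 ± 6.32 (log2 fold change 12.69, adjusted p = 0.000301). Gm10720 (chromosome 9, 3015654 to 3017210) had 0 counts in bulk and was at least 1910-fold higher in pools, with a floor of 3 counts per library. In plain CPM the mean of the passing cells was 73619.5 for Gm10800 and 52137.0 for Gm26870. A group of 13 such genes, gathered after their values were seen, took 14.4% ± 3.78 (SD, n = 3) of the counts of a cell and 0.004% ± 0.002 of bulk. Their share differed between wells: 12 passing cells outside well G12 had under 0.1%, 9 of them in retina 1a.

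**Figure D3:**
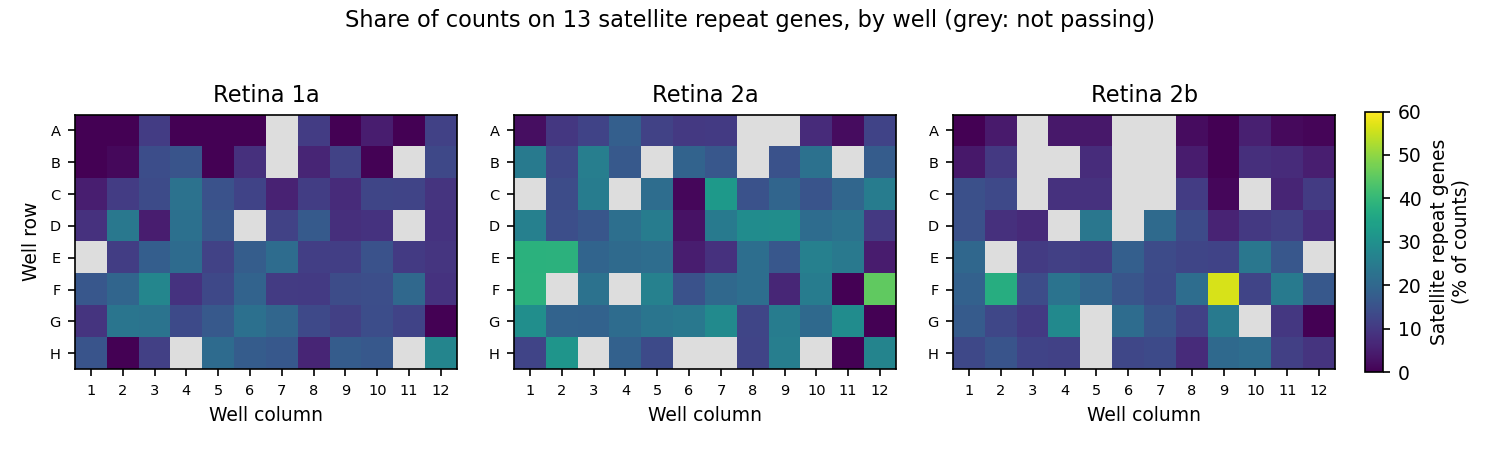
Share of the counts of each passing single-cell library on 13 satellite repeat genes (colour, percent of counts) by well row and well column of the plate of each retina; grey wells did not pass. Well G12 is near 0 on all 3 plates, and in retina 1a 9 other passing cells are under 0.1%.

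Among the 25 mitochondrially encoded genes measured, 18 were higher, 0 lower and 7 not called. There were 23 higher and 0 lower adjusted over the list alone (camera adjusted p = 8.99e-20, adjusted p = 0.604 with an estimated correlation). For the 57 nuclear genes of oxidative phosphorylation, 12 were higher, 2 lower and 43 not called. This became 14 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00455, adjusted p = 0.604 with an estimated correlation). Without retina 2b the camera adjusted p was 0.0697, so the list was not called there. Uqcrb of complex III (log2 fold change 1.69, adjusted p = 0.00898), Cox5a of complex IV (log2 fold change 1.35, adjusted p = 0.00465) and Atp5j of ATP synthase (log2 fold change 1.19, adjusted p = 0.00729) were among those that rose. The chaperone gene Hsp90aa1 (log2 fold change 1.41, adjusted p = 0.00102) and the peroxidase gene Prdx1 (log2 fold change 1.18, adjusted p = 0.00137) rose as well. Of the 82 ribosomal protein genes, 16 were higher, 1 lower and 65 not called. When adjusted over the list alone, 23 were higher and 1 lower (camera adjusted p = 0.000482, adjusted p = 0.604 with an estimated correlation). Rps3a3, which is annotated as a processed pseudogene, had 0 counts in bulk and was at least 165-fold higher in pools (adjusted p = 0.00238); its counts lie mainly in the 3 libraries of well G12, at 2032 to 4347 CPM against at most 36.2 in other passing cells. Without those 3 libraries 9 ribosomal genes rose and 1 fell of 78, with a camera adjusted p of 0.0848. Of 16 proliferation genes, 3 were higher, 0 lower and 13 not called. That made 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.15, adjusted p = 0.604 with an estimated correlation). These 3 were Cdk1, Ccnb1 and Top2a, which drive mitosis or untangle DNA; in the G12 libraries Top2a stood at 698 to 1375 CPM, and without them 0 of the 16 genes passed (edgeR), with a camera adjusted p of 0.989.

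Of 21 immediate early genes, which follow stimulation of a cell within minutes, 0 were higher, 3 lower and 18 not called. Adjusted over the list alone, 0 were higher and 4 lower (camera adjusted p = 0.000148, adjusted p = 0.604 with an estimated correlation). Jun was at 44.4 ± 14.8 CPM in pools and 169 ± 24.6 in bulk (log2 fold change -1.93, adjusted p = 0.00662), and Egr1 at 35.0 ± 18.7 and 109.8 ± 34.2 (log2 fold change -1.65, adjusted p = 0.044). Of the 9 partners of mGluR6, the glutamate receptor of ON bipolar cells, 0 were higher, 3 lower and 6 not called. The list gave 0 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.00661, adjusted p = 0.604 with an estimated correlation). Gpr179 (log2 fold change -0.64, adjusted p = 0.0117), Gnao1 (log2 fold change -0.64, adjusted p = 0.0186) and Rgs9bp (log2 fold change -0.86, adjusted p = 0.0328) were the genes that fell. Of 20 Notch pathway genes, 0 were higher, 2 lower and 18 not called. There were 0 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00465, adjusted p = 0.604 with an estimated correlation). The tests of the immediate early and Notch lists point down, with medians of -1.16 and -0.76. So does that of the Müller glia markers, with a median of -0.69 (camera adjusted p = 0.022, 0.000141 with the block and 0.0982 without retina 2b). With an estimated correlation it was 0.753, and 0.692 with the block as well. Jun, Egr1, Notch1 and Notch2 were higher in Müller glia-like than in bipolar-like cells (below), while 1 Notch pathway gene was lower there. Whether less Müller glia RNA in the pools lowered these lists was not tested. The Notch ligand gene Dll4, had 0 counts in the pools and was at least 19.3-fold lower than in bulk (adjusted p = 0.0217). The transcription factor gene Rax (log2 fold change -2.13, adjusted p = 0.0234), Wrnip1 (log2 fold change -2.12, adjusted p = 0.00211), the dynein adaptor gene Bicd2 (log2 fold change -2.11, adjusted p = 0.00386), the potassium channel subunit gene Kcnab2 (log2 fold change -1.61, adjusted p = 0.00188) and the calcium channel gene Cacna1f (log2 fold change -1.14, adjusted p = 0.0159) fell too.

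Marker lists of other cell types were compared in the same way. Of 13 Müller glia markers, 0 were higher, 0 lower and 13 not called. This became 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.022, adjusted p = 0.753 with an estimated correlation). The test of this list points down, with a median of -0.69. Apoe, a lipid carrier of glia, was at 2017 ± 867 CPM in pools and 3084 ± 585 in bulk (adjusted p = 0.274). Of 12 rod photoreceptor markers, 0 were higher, 0 lower and 12 not called. When adjusted over the list alone, 0 were higher and 0 lower (camera adjusted p = 0.501, adjusted p = 0.957 with an estimated correlation), and Rho, the rod visual pigment, was at 699 ± 301 and 834 ± 394 CPM (adjusted p = 0.73). Of 6 rod bipolar markers, 0 were higher, 2 lower and 4 not called. That made 0 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.32, adjusted p = 0.604 with an estimated correlation), the pair being Sebox (log2 fold change -0.62, adjusted p = 0.0484) and Vstm2b (log2 fold change -0.85, adjusted p = 0.0338). Neurod4 among 5 bipolar markers (log2 fold change 1.09, adjusted p = 0.00592), Scgn among 2 cone bipolar markers (log2 fold change 0.84, adjusted p = 0.0309) and Pcdh10 among 9 OFF cone bipolar markers (log2 fold change 2.15, adjusted p = 0.0369) were higher in pools. Of the vessel genes, the endothelial receptor gene Kdr was at 96.2 ± 46.9 CPM against 255 ± 60.9 in bulk (adjusted p = 0.0634), and the pericyte gene Rgs5 at 0.21 ± 0.12 against 8.64 ± 8.13 (log2 fold change -5.36, adjusted p = 0.0309).

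**Figure D4:**
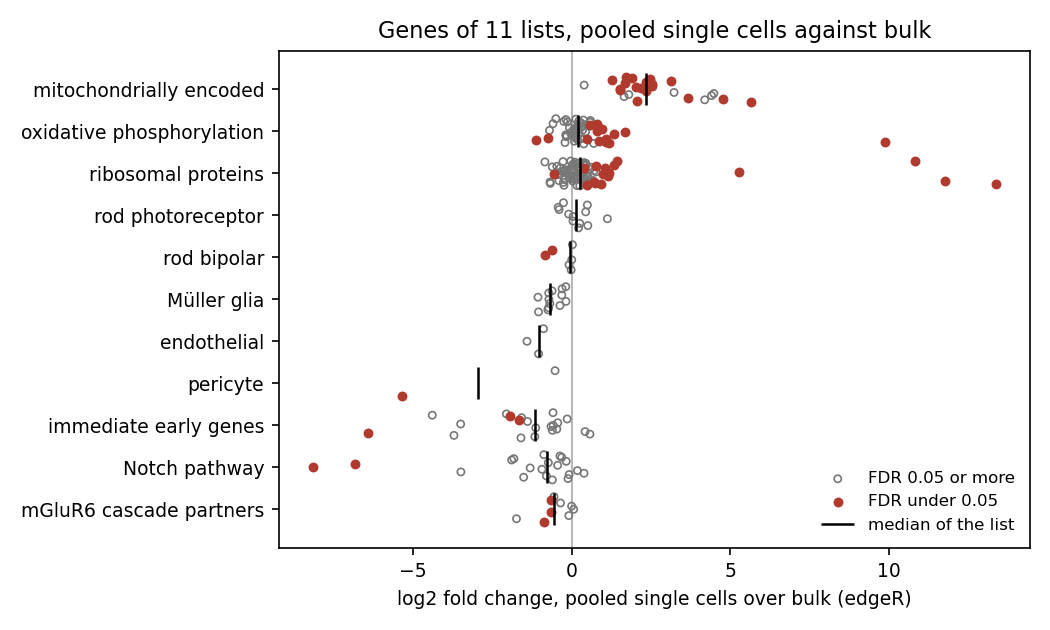
The log2 fold change of pooled single cells over bulk (horizontal axis) for the genes of 11 lists (vertical axis); each point is a gene, filled where the adjusted p is under 0.05, and black lines are list medians. All 18 called mitochondrially encoded genes lie on the side of the pools. The medians of the oxidative phosphorylation and ribosomal lists turned to -0.24 and -0.16 with the mean CPM of cells in place of summed counts. With mean TPM they turned to -0.70 and -0.60. No TMM factors were applied in these 2 settings, where the median of all genes was -0.401 and -0.642.

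In the edgeR test 1804 of 16737 genes differed at a false discovery rate of 0.05, 1105 higher and 699 lower in pools, and 1247 of them by at least 2-fold. Every gene named above as rising or falling moved the same way in 3 of 3 retinas. With retina as a block the count was 907, with DESeq2 3399, and without retina 1a, 2a or 2b it was 309, 131 or 49. On the mean of cells, limma-trend gave 789 higher and 3272 lower by mean CPM and 619 and 5569 by mean TPM. There weighting, test and, for TPM, unit all differ, and no TMM factors were applied. The median of all genes moved to -0.40 and -0.64. Which of these differences moved the median was not tested. Relative to that median the oxidative phosphorylation list stood at 0.16 and -0.06, the ribosomal list at 0.24 and 0.04 and the mGluR6 partners at -0.54 and -0.62.

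Bipolar-like cells were compared with Müller glia-like cells, the classes that the Vsx2 transgene is known to mark. Slc6a1, a GABA transporter, was at 1596 ± 303 (SD, n = 3) CPM in Müller glia-like sums and 12.7 ± 3.63 in bipolar-like sums (log2 fold change -6.98, adjusted p = 0.00323), and the peroxidase gene Prdx6 at 3179.9 ± 378 and 48.9 ± 4.64 (log2 fold change -6.02, adjusted p = 0.00134). The enolase genes parted: Eno1 was lower in bipolar-like cells (log2 fold change -3.11, adjusted p = 0.00323) and Eno2, the neuronal enolase, was higher (log2 fold change 2.92, adjusted p = 0.0361). Vsx2 was higher in bipolar-like cells, at 1149 ± 43.0 against 315 ± 44.0 CPM (log2 fold change 1.87, adjusted p = 0.0284).

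Of 11 genes of glial ion and metabolite transport, 1 was higher, 4 lower and 6 not called. Adjusted over the list alone, 1 was higher and 6 lower (camera adjusted p = 6.66e-05, adjusted p = 0.0785 with an estimated correlation). They include the carbonic anhydrase genes Car14 (log2 fold change -8.73, adjusted p = 0.0442) and Car2 (log2 fold change -2.44, adjusted p = 0.0255) and the sodium pump gene Atp1a2 (log2 fold change -8.53, adjusted p = 0.0192). Of 14 genes of glutamate and GABA uptake and metabolism, Slc6a1 among them, 1 was higher, 5 lower and 8 not called. The list gave 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.128, adjusted p = 0.376 with an estimated correlation). Of 17 antioxidant genes, 0 were higher, 3 lower and 14 not called. There were 0 higher and 5 lower adjusted over the list alone (camera adjusted p = 6.66e-05, adjusted p = 0.0785 with an estimated correlation), among them Prdx1 (log2 fold change -2.69, adjusted p = 0.0204). Of 14 immediate early genes, 0 were higher, 5 lower and 9 not called. This became 0 higher and 5 lower adjusted over the list alone (camera adjusted p = 5.81e-05, adjusted p = 0.286 with an estimated correlation). Egr1 was at 276 ± 19.6 CPM in Müller glia-like and 5.43 ± 5.02 in bipolar-like sums (log2 fold change -5.67, adjusted p = 0.0442) and Jun at 258 ± 135 and 10.6 ± 8.78 (log2 fold change -4.61, adjusted p = 0.0442). Of 18 Notch pathway genes, 1 was higher, 2 lower and 15 not called. When adjusted over the list alone, 2 were higher and 3 lower (camera adjusted p = 0.056, adjusted p = 0.286 with an estimated correlation). With retina as a block the camera adjusted p was 0.0228 (0.324 with an estimated correlation), and without 1 retina it ran from 0.0289 to 0.47. The receptor genes Notch1 (log2 fold change -7.10, adjusted p = 0.0442) and Notch2 (log2 fold change -4.04, adjusted p = 0.0299) were the lower pair in bipolar-like cells. The median of the list was -0.86 in edgeR, 1.49 by mean CPM and 0.67 by mean TPM. The median of all genes in these settings was 0.324, 0.865 and 0.8. Of 17 glycolysis genes, 5 were higher, 3 lower and 9 not called. That made 7 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.386, adjusted p = 0.778 with an estimated correlation). Aldoc (log2 fold change -2.80, adjusted p = 0.0122) and Ldhb (log2 fold change -3.82, adjusted p = 0.0227) were lower. The test of this list points down while its median is above 0. The genes Cyr61, Gpx8, Dio2 (which activates thyroid hormone), Entpd2 (which splits ATP outside cells) and Hsd17b2 had 0 counts in bipolar-like sums, which puts them at least 5370-, 4560-, 4210-, 3900- and 3150-fold lower there (adjusted p between 0.0121 and 0.0442).

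Of 29 sodium, calcium and HCN channel genes, 8 were higher, 0 lower and 21 not called. Adjusted over the list alone, 17 were higher and 0 lower (camera adjusted p = 5.44e-07, adjusted p = 0.159 with an estimated correlation). Cacna1g and Hcn3, a T-type calcium and a pacemaker channel, had 0 counts in Müller glia-like sums and were at least 79.9- and 90.9-fold higher in bipolar-like cells (both adjusted p = 0.0442). Of 15 GABA and glycine receptor genes, 5 were higher, 0 lower and 10 not called. The list gave 8 higher and 0 lower adjusted over the list alone (camera adjusted p = 5.81e-05, adjusted p = 0.0785 with an estimated correlation). Gabrr3 and Glra1 were at least 91.4- and 63.6-fold higher (both adjusted p = 0.0442). Of 23 voltage-gated potassium channel genes, 4 were higher, 0 lower and 19 not called. There were 10 higher and 0 lower adjusted over the list alone (camera adjusted p = 6.66e-05, adjusted p = 0.0785 with an estimated correlation), with Kcnd3 at least 126-fold higher (adjusted p = 0.0381). Of 33 synaptic vesicle and ribbon genes, 3 were higher, 0 lower and 30 not called. This became 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 6.66e-05, adjusted p = 0.356 with an estimated correlation). Of 46 adhesion genes, 13 were higher, 3 lower and 30 not called. When adjusted over the list alone, 18 were higher and 6 lower (camera adjusted p = 0.101, adjusted p = 0.286 with an estimated correlation), with Lrrtm4 at least 156-fold higher (adjusted p = 0.031). Gem, Gsg1, the potassium channel subunit gene Kcne2, the ion exchanger gene Slc24a4 and the homeobox gene Zfhx4 were not detected in Müller glia-like sums and were at least 488-, 380-, 340-, 330- and 251-fold higher in bipolar-like cells (adjusted p between 0.0131 and 0.0201). The mGluR6 partner Gnb3 was at 2186 ± 215 and 17.5 ± 29.1 CPM and did not pass (adjusted p = 0.101); of 8 such partners, 0 were higher, 0 lower and 8 not called. That made 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00898, adjusted p = 0.163 with an estimated correlation). Of 28 mitochondrially encoded genes, 4 were higher, 0 lower and 24 not called. Adjusted over the list alone, 4 were higher and 0 lower (camera adjusted p = 0.444, adjusted p = 0.778 with an estimated correlation). The test of these genes points down and their median was 0.23. One of them, mt-Co1, was higher in bipolar-like cells (log2 fold change 1.71, adjusted p = 0.0097), where mitochondrial transcripts took 5.61% ± 0.12 of counts in rod, 3.71% ± 0.53 in ON cone and 3.56% ± 0.09 in OFF cone bipolar-like cells, against 2.20% ± 0.52 in Müller glia-like cells. Müller glia-like cells also held 2553 ± 2367 plain CPM of rod markers, against 1103 ± 36.8 in rod bipolar-like cells.

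In the edgeR test 1196 of 14468 genes differed, 849 higher and 347 lower in bipolar-like cells, with marker genes left out and each called gene named above going the same way in 3 of 3 retinas. The Müller glia-like sum of retina 2a holds 4 cells, under the planned minimum of 5, so the comparison was run with a minimum of 4. With retina as a block the count was 24, with DESeq2 3420, without a filter on low counts 208, with a stricter filter 759, with clusters on variable genes 1819, and by mean CPM and mean TPM 2488 and 2417. Without retina 1a, 2a or 2b edgeR called 0 genes, with 3888, 3382 or 2806 at an unadjusted p under 0.05.

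Rod bipolar cells serve the rods and cone bipolar cells the cones, and the next comparison sets their transcripts side by side. Rod bipolar-like cells held more Car8, at 1177 ± 99.9 (SD, n = 3) CPM against 22.4 ± 16.5 in cone bipolar-like cells (log2 fold change 5.72, adjusted p = 0.0203), and more Nebl, at 471 ± 93.4 against 9.51 ± 4.15 (log2 fold change 5.63, adjusted p = 0.00476). The adenylyl cyclase gene Adcy1 (log2 fold change 8.59, adjusted p = 0.0362), the potassium channel partner gene Kcnip2 (log2 fold change 7.49, adjusted p = 0.0492) and the bicarbonate transporter gene Slc4a4 (log2 fold change 7.43, adjusted p = 0.00501) were higher as well. On the cone side, Kcng4, a potassium channel subunit, was at 349 ± 39.5 CPM and had 3 counts in all rod bipolar-like sums, a ratio of 9880 with a counting interval of 3380 to 47900 (adjusted p = 9e-04). The adhesion genes Igsf3 and Fat3 and the imprinted gene Mest had 0 counts in rod bipolar-like sums and were at least 883-, 846- and 684-fold lower there (adjusted p between 0.00575 and 0.0115).

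Of 22 voltage-gated potassium channel genes, 0 were higher, 6 lower and 16 not called. The list gave 1 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.00053, adjusted p = 0.159 with an estimated correlation). With 2 counts in rod bipolar-like sums, Kcnd3 had a ratio of 7180 with a counting interval of 1990 to 59300 (adjusted p = 0.00402). Of 44 adhesion genes, 2 were higher, 7 lower and 35 not called. There were 8 higher and 19 lower adjusted over the list alone (camera adjusted p = 0.00053, adjusted p = 0.159 with an estimated correlation). Cdh8 was at 139 ± 53.5 CPM in cone and 0.13 ± 0.13 in rod bipolar-like cells (log2 fold change -10.04, adjusted p = 0.00563), and Pcdh7 was at least 133-fold lower in rod bipolar-like cells (adjusted p = 0.0348). Of 17 ionotropic glutamate receptor genes, 0 were higher, 2 lower and 15 not called. This became 0 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00827, adjusted p = 0.184 with an estimated correlation). Gria2 of the AMPA receptor was at 12.7 ± 3.6 CPM in rod and 254 ± 97.8 in cone bipolar-like cells (log2 fold change -4.33, adjusted p = 0.00695). In the 16 GABA and glycine receptor genes, 0 were higher, 2 lower and 14 not called. When adjusted over the list alone, 1 was higher and 4 lower (camera adjusted p = 0.00827, adjusted p = 0.159 with an estimated correlation), and Gabrb1, with 1 count in rod bipolar-like sums, had a ratio of 4540 with a counting interval of 815 to 179000 (adjusted p = 0.00695). Receptors for neuromodulators went both ways: Adrb1 was at least 350-fold higher in rod bipolar-like cells (adjusted p = 0.0163) and Htr3a at least 585-fold lower (adjusted p = 0.0253). Over the 12 of that list, 1 was higher, 1 lower and 10 not called. That made 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.202, adjusted p = 0.308 with an estimated correlation). In the 5 gap junction genes, 0 were higher, 0 lower and 5 not called. Adjusted over the list alone, 0 were higher and 2 lower (camera adjusted p = 0.00859, adjusted p = 0.159 with an estimated correlation). Gjd2 was at 0.84 ± 1.43 and 174 ± 12.5 CPM (adjusted p = 0.0782).

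Of 8 partners of mGluR6, 2 were higher, 0 lower and 6 not called. The list gave 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000837, adjusted p = 0.159 with an estimated correlation), with Gpr179 at 593 ± 57.0 against 181 ± 13.8 CPM (log2 fold change 1.71, adjusted p = 0.00632) and Gnao1 at 720.3 ± 71.9 against 299 ± 80.6 (log2 fold change 1.27, adjusted p = 0.0391). The cone bipolar-like sums hold both ON and OFF cells. The 8 partners together stood at 5323.9 CPM in rod and 3182.9 in cone bipolar-like cells. In the comparison of ON with OFF cone bipolar-like cells they stood at 4498.1 and 981.1. Rod bipolar-like cells were not tested against ON cone bipolar-like cells alone. The calcium channel subunit gene Cacna2d3 (log2 fold change 2.42, adjusted p = 0.0102) and the synaptic genes Lin7a (log2 fold change 1.49, adjusted p = 0.021) and Snap25 (log2 fold change 0.95, adjusted p = 0.00575) were higher and the complexin gene Cplx4 (log2 fold change -2.59, adjusted p = 0.0362) was lower. Of 29 mitochondrially encoded genes, 5 were higher, 0 lower and 24 not called. There were 13 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.75e-09, adjusted p = 0.159 with an estimated correlation). Both mt-Co1 (log2 fold change 0.79, adjusted p = 0.014) and mt-Co3 (log2 fold change 0.88, adjusted p = 0.0217) were higher in rod bipolar-like cells. Among 57 oxidative phosphorylation genes, 1 was higher, 0 lower and 56 not called. This became 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.55e-06, adjusted p = 0.175 with an estimated correlation), the called gene being Sdha (log2 fold change 0.94, adjusted p = 0.0434). Of 17 glycolysis genes, 0 were higher, 3 lower and 14 not called. When adjusted over the list alone, 0 were higher and 10 lower (camera adjusted p = 3.98e-09, adjusted p = 0.159 with an estimated correlation). Pkm (log2 fold change -0.85, adjusted p = 0.0353), Aldoc (log2 fold change -1.46, adjusted p = 0.0241) and Ldhb (log2 fold change -2.47, adjusted p = 0.047) were lower. Of 16 antioxidant genes, 1 was higher, 0 lower and 15 not called. That made 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00357, adjusted p = 0.159 with an estimated correlation), with the metallothionein gene Mt1 higher (log2 fold change 2.46, adjusted p = 0.0148). Of 12 immediate early genes, 0 were higher, 0 lower and 12 not called. Adjusted over the list alone, 2 were higher and 0 lower (camera adjusted p = 0.00357, adjusted p = 0.184 with an estimated correlation). Vsx2 was at 1536 ± 227 CPM in rod and 877 ± 177 in cone bipolar-like cells (adjusted p = 0.0896).

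**Figure D5:**
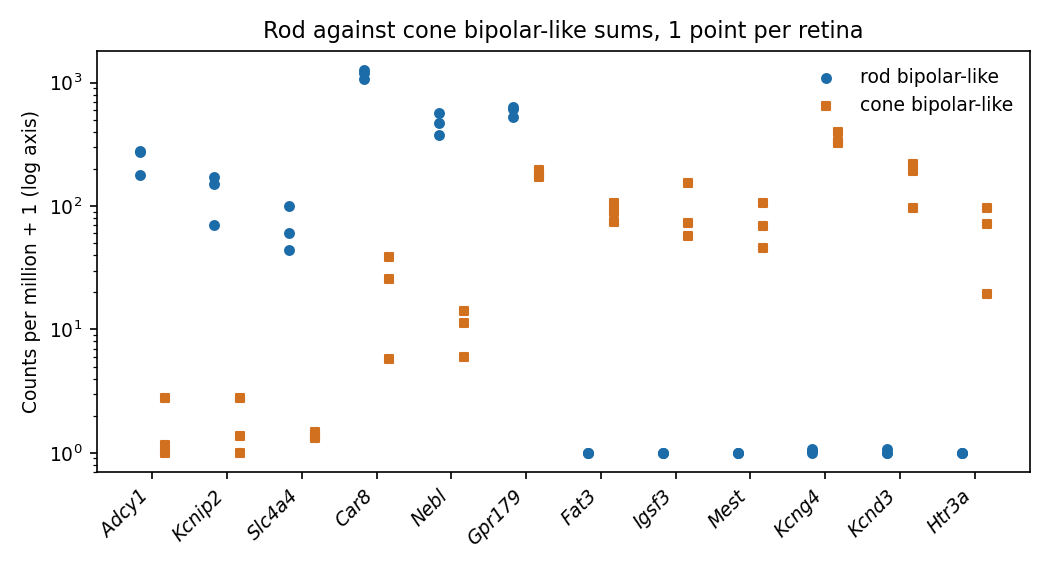
Normalised CPM plus 1 (vertical log axis) of 12 named genes (horizontal axis) in the summed rod bipolar-like cells (circles) and cone bipolar-like cells (squares), 1 point per retina. Car8 stood at a mean of 1177 ± 99.9 against 22.4 ± 16.5 CPM, and Fat3, Igsf3, Mest and Htr3a had 0 counts in rod bipolar-like cells.

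In the edgeR test 382 of 14168 genes differed, 162 higher and 220 lower in rod bipolar-like cells, 365 of them by at least 2-fold and each called gene named above in the same direction in 3 of 3 retinas. With retina as a block the count was 20, with DESeq2 1272, without a filter on low counts 199, with clusters on variable genes 597, and by mean CPM and mean TPM 668 and 604. Without retina 1a, 2a or 2b edgeR called 6, 8 or 0 genes, the last with 1700 at an unadjusted p under 0.05.

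ON and OFF cone bipolar cells respond to light with opposite signs, and their sums differed in 9 genes. In ON cone bipolar-like cells Prox1, a homeobox gene, was at 510.0 ± 64.6 (SD, n = 3) CPM against 69.9 ± 15.7 in OFF cone bipolar-like cells (log2 fold change 2.87, adjusted p = 0.0449). The growth factor gene Tgfb2 (log2 fold change 9.65, adjusted p = 0.0184), St18 (log2 fold change 9.93, adjusted p = 0.0462), Rnf152 (log2 fold change 9.04, adjusted p = 0.0449), Hs3st4 (log2 fold change 7.42, adjusted p = 0.0462) and Medag (log2 fold change 7.19, adjusted p = 0.0201) were higher too. Ptprt, a receptor phosphatase gene with 3 counts in OFF cone bipolar-like sums, had a ratio of 1240 with a counting interval of 425 to 6020 (adjusted p = 0.0462). Lower in ON cone bipolar-like cells were Fam19a3, at 112 ± 13.7 against 664 ± 157 CPM (log2 fold change -2.57, adjusted p = 0.0462), and the glycogen phosphorylase gene Pygl, which had 1 count in ON cone bipolar-like sums and a ratio of 6180 with a counting interval of 1110 to 244000 (adjusted p = 0.0449).

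Of 8 mGluR6 partners, 0 were higher, 0 lower and 8 not called. The list gave 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000264, adjusted p = 0.261 with an estimated correlation). Without retina 2a the camera adjusted p was 0.075, so the list was not called there. Gnb3, a G protein subunit of that cascade, was at 2827 ± 441 CPM in ON and 239 ± 136 in OFF cone bipolar-like cells (adjusted p = 0.0798). Kcng4 was at 499 ± 91.5 CPM in ON and 100.01 ± 35.3 in OFF cone bipolar-like cells (adjusted p = 0.092), the connexin gene Gjd2 at 252 ± 34.1 and 45.2 ± 16.6 (adjusted p = 0.092), the calcium channel subunit gene Cacna2d4 at 813 ± 49.8 and 434 ± 18.5 (adjusted p = 0.125) and Vsx2 at 952 ± 329 and 844 ± 119 (adjusted p = 1). Of 20 voltage-gated potassium channel genes, 0 were higher, 0 lower and 20 not called. There were 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.139, adjusted p = 0.416 with an estimated correlation), and of 11 neuromodulator receptor genes, 0 were higher, 0 lower and 11 not called. This became 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.142, adjusted p = 0.416 with an estimated correlation).

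The 9 genes were called by edgeR among 12254, 7 higher and 2 lower in ON cone bipolar-like cells, each in the same direction in 3 of 3 retinas. With retina as a block, and without retina 1a, 2a or 2b, edgeR called 0 genes, with 800, 1114, 1138 and 1107 at an unadjusted p under 0.05. DESeq2 called 581, a stricter filter 30, no filter 2, mean CPM 106, cells of at least 2000 genes 15, clusters on variable genes 28 and a Leiden resolution of 2 also 15. Mean TPM called 8, with 1 of the 9 genes among them, and the setting without well G12 called 8, with 6 of the 9.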

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

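The tests in this part were chosen after the values were seen, except that of the satellite share of well G12. Signals outside the comparisons of the report were looked for in the libraries under the cell filter, in well G12 and in the unnamed cluster.

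The 39 single-cell libraries under the cell filter had a median of 6.14% of counts on mitochondrially encoded genes, against at most 1.39% in bulk, and 23 of the 39 were above that bulk value. The passing cells had a median of 4.19%.

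The 3 libraries of well G12, 1 on each plate, held the embryonic globins Hbb-y and Hbb-bh1 at 4141 CPM or more together, against 0 in bulk. They had 0 counts of Rho and Vsx2, and their lowest correlation with each other was 0.724, against at most 0.53 between any other 2 cells. A chance mislabelled or contaminated well is argued against, since the pattern stands in well G12 on 3 of 3 plates and in 0 other wells; a control placed there on purpose, which the sample labels do not name, was not tested and stays open. RNA from another organism read against the mouse annotation may be the source: processed pseudogenes took at least 2.252% of the counts of each G12 library, against at most 0.918% in the other passing cells. A mouse retinal cell of another type, left open by the satellite shares (at most 0.0008% in these libraries, at least 0.0004% in the other cells), is argued against by bulk: at 0.249% of cells, the exact lower bound for 3 of 249, cells alike in RNA content would bring 10.32 CPM of the 2 globins to bulk, where 0 counts allow at most 0.283.

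Satellite repeat genes took 14.4% ± 3.78 (SD, n = 3) of the counts of cells and 0.004% ± 0.002 of bulk. A cell class that bulk lacks is argued against, since the lowest class mean was 3414.8 times the bulk mean. So are a few libraries of extreme composition, since the median cell of each retina was at least 3042 times the bulk mean. Genomic DNA in the lysates of single cells could raise these genes, and cells had 1.97 to 3.22 times the olfactory receptor CPM of bulk. It stays open, because the 9 cells of retina 1a with under 0.1% on satellite genes had olfactory receptor CPM of 87.0 ± 81.5 (SD, n = 9) against 80.6 ± 71.6 in the 78 others, a difference of 6.4 with a standard error of 28.4; no biological explanation was tested.

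Clusters made without well G12 put 24 cells in the unnamed rod-marker cluster, and the values here are of the main setting. In it the 15 cells of the unnamed cluster outside well G12 had a median of 23292 CPM of rod markers, against 4847, 2300.4 and 2503 in the bulk libraries of retinas 1a, 2a and 2b. Of these cells 10 held both Rho and Vsx2 (5, 3 and 2 in retinas 1a, 2a and 2b) and 5 had no Vsx2 count. Whether 2 cells fell in 1 well stays open: the median at 50000 counts was 3441 genes in the 10 cells against 3061 in the 94 bipolar-like cells that hold both genes too, and by retina it was 3495 against 3079.5 in 1a, 3514 against 3017 in 2a and 2377 against 3120.0 in 2b. Free rod RNA in every well stays open as a part of the signal: the median rod marker level of all cells with a Vsx2 count was 3.51% of the 19477 CPM median of the 10 cells. Rod fragments attached to bipolar cells, and a bipolar cell that expresses rod genes, were not tested.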

How the results depend on the processing

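The settings without well G12, the unnamed cluster or the satellite genes, and the minimum of 4 cells for Müller glia-like sums, were chosen after seeing the data. Of 156 values of results under alternatives 87 moved by less than the spread or 1.5 times and 69 moved by more; the cause was not tested unless named here.

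For pooled cells with bulk the count of 1804 genes became 3399 with DESeq2, 907 with retina as a block, 4061 by mean CPM and 6188 by mean TPM. For bipolar-like with Müller glia-like cells 1196 became 3420, 24, 2488 and 2417, and for rod with cone bipolar-like cells 382 became 1272, 20, 668 and 604. For ON with OFF cone bipolar-like cells 9 became 581 with DESeq2, 0 with the block in edgeR (800 at an unadjusted p under 0.05) and 106 by mean CPM. By mean TPM it was 8, but only 1 of the 9 genes was among them, and without well G12 it was 8 with 6 of the 9. Without a filter on low counts the counts of the last 3 comparisons became 208, 199 and 2, where more genes were tested. With at least 10 CPM in 3 sums they were 759 for bipolar-like with Müller glia-like and 30 for ON with OFF. Clusters on variable genes gave 1819, 597 and 28. The ON with OFF count was 15 with cells of at least 2000 genes and 15 at a Leiden resolution of 2. Leaving out 1 retina, with fewer samples, gave 49 to 309, 0 to 0, 0 to 8 and 0 to 0 genes (edgeR).

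With an estimated correlation camera called 0 lists in all 4 comparisons; fry called 17 lists for bipolar-like with Müller glia-like cells and 4 for ON with OFF. Leaving out 1 retina gave 6 to 7, 9 to 12, 10 to 12 and 0 to 2 lists. Bipolar-like with Müller glia-like cells was not run with cells of at least 2000 genes (3 Müller glia-like cells in retina 2a), nor ON with OFF at a resolution of 0.5 (4 OFF cells in 1a).

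Without a cell filter the shares were 37.5% rod bipolar-like, 18.75% ON cone, 12.5% OFF cone and 68.75% for the 3 bipolar-like classes (198 cells, against 207 in the main setting), and 44 cells, 15.28%, stood in clusters that fit no class. With cells of at least 2000 genes ON cone was 22.14%, OFF cone 16.38% and the unnamed cluster 8.2%; with clusters on variable genes they were 27.63%, 17.19% and 4.88%. At a Leiden resolution of 0.5 OFF cone was 6.89%, the unnamed rod-marker cluster 0.0%, clusters that fit no class 14.77% and the 3 classes together 75.7%; at 2 the unnamed cluster was 5.28%. Without well G12 ON cone was 21.93% (54 cells, against 63 in the main setting) and the unnamed cluster 9.81% (24 cells). The rod bipolar-like, OFF cone and Müller glia-like classes kept 108, 36 and 24 cells. Leaving out 1 retina gave 42.18% to 45.37% rod bipolar-like, 24.11% to 26.03% ON cone, 13.8% to 15.22% OFF cone, 6.9% to 11.87% Müller glia-like, 7.02% to 7.46% unnamed and 80.87% to 85.64% for the 3 classes. The comparisons of classes gave the same values without a cell filter as without well G12, since 222 of 222 named cells had the same class in both.

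The correlation of all cells with bulk was 0.9099 with a pseudocount of 0.1, 0.855 over genes of at least 10 TPM in bulk and 0.9528 with CPM, and 0.9288 to 0.9347 without 1 retina. Genes per cell were 3367 at an expected count of at least 5, 4586.3 at a TPM of at least 1, 3061 and 4039.3 after thinning to 50000 and 200000, 4911.2 without a cell filter, and 4989.5 to 5009.5 without 1 retina.

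Of 1744 values of named genes under alternatives 1282 kept direction and side of the threshold, 430 fell short of it, 30 newly passed it and 2 turned: Rho in pooled cells with bulk without retina 1a (0.36 on the log2 scale; range without 1 retina -0.84 to 0.36) and Vsx2 in ON with OFF without retina 2a (-0.17; range -0.17 to 0.5), neither called. With the block 24 of 37 named genes stayed called for pooled cells with bulk, 4 of 33 for bipolar-like with Müller glia-like, 3 of 31 for rod with cone and 0 of 14 for ON with OFF.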

Other observations

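The clusters and genes described here were chosen after their values were seen, and the tests of other splits were set before.

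The bipolar-like classes hold more than 1 cluster each. Of the ON cone bipolar-like cells, 26 stood in a cluster led by Ptprt, Htr3a (a serotonin receptor channel) and Kcng4, 12 in one led by Slitrk5 and Gabrr3, and 25 in one led by Vsx1, Reln and Cck. Their Vsx2 levels were 1155 ± 444, 1465 ± 350.4 and 379 ± 148 CPM (SD, n = 3 retinas). OFF cone bipolar-like cells formed a cluster of 19 led by Tacr3, the neurokinin receptor, and Slit2, and a cluster of 17 led by Grik1, a kainate receptor, and Gsg1. Vsx2 stood at 671 ± 102 in the first and 999 ± 161 CPM in the second. Rod bipolar-like cells fell into clusters of 54, 30 and 24 cells, which all had Prkca, Pcp2 and Car8 among the 10 genes with the largest difference in mean log level from the other clusters. The cone clusters are described by fold. Among the first 10 genes by fold the rod bipolar-like clusters had 0, 1 and 0 of their own markers. Prkca, Pcp2, Slitrk5, Vsx1, Cck, Tacr3 and Grik1 are markers that formed the clusters, so their lead is no separate evidence for the classes. No test between clusters of a class was made.

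The nuclear RNA Malat1 was at 11181 ± 1408 CPM in Müller glia-like cells, 7164 ± 948 in rod bipolar-like, 5461 ± 1011 in ON cone and 4327 ± 621 in OFF cone bipolar-like cells (SD, n = 3), against 2077 ± 143 in bulk. The homeobox gene Otx2 was found in 92.6% of 108 rod bipolar-like and 12.5% of 24 Müller glia-like cells.

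Each comparison of 3 with 3 sums has 10 splits, which are too few for a share under 0.05. The real split called 1804, 1196, 382 and 9 genes with edgeR in the 4 comparisons, in the order of the report, and the highest other split called 0 in each. Every other split holds sums of both real groups on each side, so a difference between the groups widens its spread within sides. The 0 calls therefore cannot decide whether chance gave the real counts. At an unadjusted p under 0.05 the other splits had 203 to 466, 120 to 200, 363 to 548 and 305 to 406 genes. As many genes as the real split came from 1 of the 10 splits in each comparison. For gene lists by camera, 4 of the 10 splits gave at least the 7 lists of pooled cells with bulk (highest other 8), 1 gave the 11 of bipolar-like with Müller glia-like cells (highest other 9), 1 gave the 11 of rod with cone (highest other 5) and 2 gave the 1 of ON with OFF (highest other 1). Of the other splits 3 part all 3 pairs, as the real one does.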
